A study of Mus musculus with 10 samples.

How the data were processed

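The series holds 10 Agilent 2-colour arrays of mouse liver RNA. Per the labels' protocols, female C57BL/6 mice aged 8 weeks were fasted for 24 h and then given a single intraperitoneal injection of acetaminophen at 350 mg/kg, or of its saline vehicle, and livers were taken 3, 8, 24, 48 or 72 h later. Each array carried RNA of a control mouse in the Cy3 channel and RNA of a treated mouse in the Cy5 channel, with 2 arrays per time point, and the labels number the mice as separate animals. The dyes were never exchanged, so a dye effect of a probe cannot be told apart from the treatment at any single time point, whereas a dye effect that is the same on every array cancels in differences between time points.

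Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1, and the deposited files give, for each spot, the mean intensity and the median background intensity of both channels on a linear scale. The same deposited files give the log10 ratio of Cy5 over Cy3 after the software's own background and dye correction, and flags for spots well above background, saturated spots and outliers. The deposited value table of the authors holds a score on an unstated scale. Set against the scanner files, its values were 1.44 times the log10 ratio on every array, with a correlation of 1 and a median of 0 on each array, so it runs as treated over control and is in neither log10 nor log2 units. Between 8.85% and 26.6% of its values per array were exactly 0. It was rescaled to log2 and used as an alternative.

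Mean intensities were background-corrected with normexp (offset 50) and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess, in limma 3.58.1 under R 4.3.3. The 1377 control spots and the outlier-flagged spots had weight 0 in the loess, and 2718 outlier-flagged spots over all arrays were left out afterwards. No scaling was applied between arrays. Spots of the same probe were averaged, which concerned 399 probes. A probe was kept when it was well above background in the same channel on both arrays of at least 1 time point, which left 29467 of 39429 probes. Of the 39429 probes, 26581 were named through their accession in the mouse RefSeq table (assembly GRCm38.p6), 2597 carried a current symbol, 492 carried an older symbol of a single gene, and 9759 kept the name in the file. Each gene was represented by its brightest kept probe, giving 23914 genes tested, 17560 of them with a symbol of the reference. Among 4589 genes with more than 1 kept probe, 92 had probes called in opposite directions at some time point. Probe coordinates are those of the files (mm9), and whether a probe lies in an exon or a UTR was not analysed here. Whether each probe lies at the gene it is named for was not checked throughout. The brightest-probe rule gave mean log2 intensities of 16.4 for Cxcl11 (cytokine list) and 14.1 for Csf3r (neutrophil list), against 17.2 for Alb. Whether these signals are those of the named genes was not tested.

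Genes were tested with lmFit and eBayes of limma over all 10 arrays, with a coefficient per time point and 5 residual degrees of freedom, and two-sided p-values were adjusted by the Benjamini-Hochberg method at 0.05. A coefficient against 0 gave the genes changed at a time point, 4 contrasts gave the differences between neighbouring time points, and a moderated F test gave any difference between time points. Control livers were examined in the Cy3 channel alone after loess and Aquantile scaling, by an F test over time and by each later time point minus 3 h. In all, 34 gene lists fixed before the data were examined were tested at the 5 time points with camera at a preset inter-gene correlation of 0.01, adjusted over 170 tests. Of these, 79 were called. With the correlation estimated from the data, 0 of the 79 calls held. The test fry, which asks only whether a list's genes move on balance one way, called 55 of the 170. Of its calls, 7 of 8 at 3 h and 16 of 17 at 24 h were also camera calls in the same direction, as were all at the other time points. Counts "adjusted over the list alone" apply the adjustment within a list. Values are log2 ratios of treated over control ± SE of the fit, n = 2 arrays per time point, unless stated otherwise. A probe not well above background on both arrays of a channel has only a bound there, given as "at least N-fold" from channel levels after loess and Aquantile, and this bound is open to dye bias.

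Genes were named by a rule fixed before the data were examined: the 6 largest rises and 6 largest falls at each time point among genes with a symbol that were called and moved the same way on both arrays, up to 4 called members of each called list in its direction and up to 2 against it, the 2 largest changes of a list not called, the 8 smallest p-values of the F test, the 3 largest changes each way between neighbouring time points, the 5 largest changes each way in control livers at 24 and 72 h against 3 h among genes past the F test, and a fixed panel of 14 genes. Some genes that met this rule are not reported here. The gene tests were checked on simulated ratios of all 23914 genes, with independent normal noise and each gene's real spread pooled over time points. At each time point 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale. These are far fewer than the genes called in the data at 3, 8, 24 and 48 h. The shares recovered and the shares of false calls may therefore differ in the real tests. At 72 h, 31.3% of simulated changes of 0.5 on the log2 scale, 70.1% of changes of 1 and 100% of changes of 2 were recovered, and at 3 h 37.3%, 89.6% and 95.5%. In this single simulation 15 of 163 calls at 3 h, 9 of 142 at 8 h, 5 of 144 at 24 h, 5 of 144 at 48 h and 11 of 145 at 72 h were false. These shares of 9.20%, 6.34%, 3.47%, 3.47% and 7.59% lay above the threshold of 0.05 at 3, 8 and 72 h.

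Signal was well above background at 60.4% to 84.1% of 43020 non-control spots per array in Cy3 and at 45.1% to 76.6% in Cy5, and no spot was saturated. The number of arrays limits the precision. The arrays lay on 4 slides and were scanned on 2 days, each day holding 1 array of every time point, so the scan day coincides with the replicate number. Alternatives covered the background correction, the software's own ratios, the authors' value table, median centring, Aquantile scaling, the filters, the probe rule, the variance prior, array weights, the arrays in the fit, the scan day and slide as blocks, leaving out each array, and a contrast of each time point with the mean of the others. Leaving out both 72 h arrays was added after seeing the data.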

Results

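Gene expression was measured in livers of fasted female mice given 350 mg/kg acetaminophen, a drug whose overdose injures the liver through a metabolite made largely by cytochrome P450 enzymes, or vehicle. At each of 3, 8, 24, 48 and 72 h, 2 arrays each compared a treated with a control liver. Across genes, which are not independent replicates, the log2 ratios of the 2 arrays correlated at 0.68 at 3 h, 0.80 at 8 h, 0.76 at 24 h, 0.86 at 48 h and 0.27 at 72 h. Of 23914 genes, 1784 changed at 3 h, 3090 at 8 h, 2604 at 24 h, 7513 at 48 h and 0 at 72 h, and every called gene moved the same way on both arrays, and so on both scan days.

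**Figure D1:**
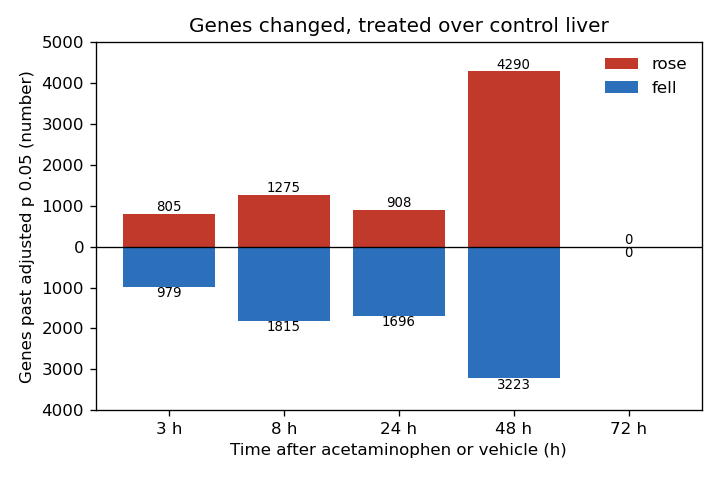
Genes past an adjusted p of 0.05 at each time point (x axis, hours), with genes that rose above 0 and genes that fell below it (y axis, number of genes, 2 arrays per time point). The counts are largest at 48 h, with 4290 rises and 3223 falls, and 0 at 72 h, while with median centring they were largest at 3 h.

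The earliest comparison asked which genes had responded by 3 h. The largest rise of a called gene with a symbol was that of Igfbp1, which encodes a binding protein of insulin-like growth factors (probe at chromosome 11, 7102442 to 7102501), with a log2 ratio of 6.15 ± 0.51. The metallothionein gene Mt2 was at 5.51 ± 0.42. The immediate early transcription factor genes Egr1 and Jun rose by 5.46 ± 0.26 and 4.49 ± 0.17, the stress cytokine gene Gdf15 by 4.69 ± 0.22 and Rgs16 by 4.48 ± 0.25. The deepest fall was that of Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6193456 to 6193515), at -3.66 ± 0.48. It was followed by Cish at -2.59 ± 0.23, the chaperone gene Hsph1 at -2.49 ± 0.16, Clec2d at -2.44 ± 0.24, Phlda1 at -2.38 ± 0.20 and Creld2 at -2.32 ± 0.18. In all, 805 genes rose and 979 fell, 250 and 137 of them at least 2-fold.

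Of 36 immediate early genes, 16 rose, 0 fell and 20 did not pass at 3 h, with 19 rising when adjusted over the list alone (camera, adjusted p = 5.7e-16, adjusted p = 0.119 with an estimated correlation). Nr4a1 and Btg2 rose by 3.23 ± 0.38 and 2.98 ± 0.11. Of 24 heat shock genes, 8 fell and 0 rose, or 14 and 1 adjusted over the list alone (adjusted p = 4.11e-08, adjusted p = 0.119 with an estimated correlation). The chaperone genes Hsp90aa1 and Chordc1 stood at -1.62 ± 0.26 and -1.64 ± 0.13. Of 40 ribosome biogenesis genes, 12 fell and 0 rose, or 20 and 1 adjusted over the list alone (adjusted p = 4.04e-11, adjusted p = 0.236 with an estimated correlation). Nop2 was at -1.25 ± 0.12 and Pno1 at -0.80 ± 0.14. In the interferon response list 3 of 37 genes fell, the same 3 adjusted over the list alone (adjusted p = 0.000668, adjusted p = 0.636 with an estimated correlation). These were Igtp at -1.08 ± 0.25, Irgm1 at -1.04 ± 0.14 and Irf1 at -0.97 ± 0.13.

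Among 38 targets of NRF2, the regulator of antioxidant genes, 7 rose and 0 fell at 3 h, or 10 and 0 adjusted over the list alone (adjusted p = 1.49e-06, adjusted p = 0.217 with an estimated correlation). Hmox1, which degrades haem, rose by 2.95 ± 0.19 and Osgin1 by 1.32 ± 0.28. Of 24 periportal hepatocyte genes, 6 rose and 1 fell, or 11 and 1 adjusted over the list alone (adjusted p = 3.7e-06, adjusted p = 0.119 with an estimated correlation). Sds was at 2.48 ± 0.14 and the gluconeogenic gene Pck1 at 1.66 ± 0.15. Of 35 gluconeogenesis and glycolysis genes, 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.019, adjusted p = 0.373 with an estimated correlation). G6pc, which releases glucose, led them at 2.89 ± 0.27. The direction of these 3 lists flipped with median centring in place of loess, which gave medians of -0.46, -0.56 and -0.90 against a median of all genes of -0.24, and none of the 3 was then called. Genes of female-biased and male-biased liver expression fell in 4 of 29 cases and rose in 1, or 7 and 2 adjusted over the list alone (adjusted p = 0.0188, adjusted p = 0.402 with an estimated correlation). Those that fell included the growth hormone response genes Cish and Socs2, the latter at -1.04 ± 0.14.

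Of 32 G2 and mitosis genes, 2 rose and 0 fell, or 1 and 0 adjusted over the list alone (adjusted p = 0.00761, adjusted p = 0.41 with an estimated correlation). These were Hmgb2 at 1.16 ± 0.14 and Cdk1, the mitotic kinase, at 0.78 ± 0.19. Of 30 lymphocyte genes 1 rose, Cd22 at 0.34 ± 0.06, also adjusted over the list alone, and 0 fell (adjusted p = 0.0488, adjusted p = 0.582 with an estimated correlation). With median centring Cd22 was at -0.12. The list of p53 targets was not called at 3 h, with 7 rises and 5 falls among 33 genes, or 9 and 9 adjusted over the list alone (adjusted p = 0.316). Its members Trp53inp1 and Cdkn1a, a cell cycle inhibitor, had log2 ratios of 3.45 ± 0.12 and 3.40 ± 0.27. Median centring gave 1005 rises and 5018 falls at 3 h, the software's own ratios gave 1058 genes, and the slide as a block left 321 genes and ended the calls of the mitosis, gluconeogenesis and lymphocyte lists. Without 3 h replicate 1 the count was 403 and the interferon call ended. Without 3 h replicate 3 the count was 1127 and the calls of the mitosis, sex-biased, gluconeogenesis and lymphocyte lists ended. An offset of 0 ended the gluconeogenesis and lymphocyte calls, no filter on dim probes the mitosis and lymphocyte calls, and an intensity trend the sex-biased call. The lymphocyte call also ended with the software's own ratios, the stricter filter and median centring, and without any single 8, 24 or 72 h array. Of the 10 calls, 3 held under every alternative of processing, block and left-out array: immediate early, heat shock and ribosome biogenesis.

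At 8 h the rises included immediate early, antioxidant and acute phase genes and single chemokine genes, and the falls included part of the lipid synthesis genes. Egr1 had a log2 ratio of 5.95 ± 0.26, Ifrd1 5.24 ± 0.29, Igfbp1 5.21 ± 0.51, Jun 5.09 ± 0.17, Mt2 4.89 ± 0.42 and Cxcl10, a chemokine gene, 4.70 ± 0.26. The deepest falls were those of Tmem25 at -2.85 ± 0.35, Clec2d at -2.49 ± 0.24, Cyp7a1 at -2.47 ± 0.48, Noct at -2.26 ± 0.36, Hes6 at -2.26 ± 0.17 and the fatty acid elongase gene Elovl6 at -2.21 ± 0.29. In all, 1275 genes rose and 1815 fell, 393 and 232 of them at least 2-fold.

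At 8 h, 24 of 36 immediate early genes rose and 0 fell, or 29 and 0 adjusted over the list alone (adjusted p = 1.63e-25, adjusted p = 0.107 with an estimated correlation). Fos was at 4.39 ± 0.42 and Maff at 3.94 ± 0.36. NRF2 targets rose in 19 of 38 cases with 0 falls, or 21 and 1 adjusted over the list alone (adjusted p = 1.75e-13, adjusted p = 0.119 with an estimated correlation). Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, reached 3.31 ± 0.27 and the glutathione transferase gene Gsta1 3.16 ± 0.62. Of 39 integrated stress and unfolded protein response genes, 18 rose and 7 fell, or 20 and 10 adjusted over the list alone (adjusted p = 2.92e-05, adjusted p = 0.322 with an estimated correlation). Chac1 and Atf3 rose by 4.45 ± 0.29 and 3.43 ± 0.40, whereas Sdf2l1 and Pdia4, which act in the endoplasmic reticulum, stood at -1.24 ± 0.18 and -1.20 ± 0.12. Among 33 p53 targets 10 rose and 4 fell, or 13 and 4 adjusted over the list alone (adjusted p = 5.28e-05, adjusted p = 0.112 with an estimated correlation). Gdf15 was at 4.31 ± 0.22, Plk3 at 2.83 ± 0.22 and Ccnd1, a G1 cyclin, at -1.30 ± 0.15.

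Acute phase genes rose in 18 of 40 cases and fell in 1 at 8 h, or 19 and 2 adjusted over the list alone (adjusted p = 1.38e-08, adjusted p = 0.058 with an estimated correlation). Saa2 and Lcn2 had log2 ratios of 2.31 ± 0.31 and 2.28 ± 0.25. Of 36 cytokine and chemokine genes 4 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0219, adjusted p = 0.236 with an estimated correlation). These were Cxcl10, Cxcl1 at 3.15 ± 0.25, Hbegf at 1.06 ± 0.14 and Areg. Areg, whose control signal was not well above background, was at least 1.39-fold higher. Cxcl10 also belongs to the interferon response list, in which it rose while 8 of 37 genes fell, or 1 and 13 adjusted over the list alone (adjusted p = 0.000358, adjusted p = 0.615 with an estimated correlation). Stat2 was at -1.08 ± 0.14. Of 27 hypoxia genes 9 rose and 0 fell, or 13 and 0 adjusted over the list alone (adjusted p = 4.64e-06, adjusted p = 0.131 with an estimated correlation). Plin2, which coats lipid droplets, was at 2.68 ± 0.35 and Ddit4 at 2.34 ± 0.20.

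Of 27 fatty acid synthesis genes 11 fell and 2 rose at 8 h, or 15 and 2 adjusted over the list alone (adjusted p = 5.21e-05, adjusted p = 0.307 with an estimated correlation). Mid1ip1 was at -2.15 ± 0.24 and fatty acid synthase, Fasn, at -1.40 ± 0.22. In the cholesterol synthesis list 5 of 27 fell and 0 rose, or 9 and 0 adjusted over the list alone (adjusted p = 2.92e-05, adjusted p = 0.534 with an estimated correlation). Sc5d was at -1.50 ± 0.19. Heat shock genes rose in 10 of 24 cases and fell in 4, or 13 and 7 adjusted over the list alone (adjusted p = 0.0379, adjusted p = 0.41 with an estimated correlation). Dnajb1 was at 3.25 ± 0.31. Ribosome biogenesis genes rose in 15 of 40 cases with 0 falls, or 16 and 1 adjusted over the list alone (adjusted p = 1.96e-07, adjusted p = 0.343 with an estimated correlation). Fatty acid oxidation genes rose in 10 of 42 cases with 0 falls, or 14 and 0 adjusted over the list alone (adjusted p = 0.00187, adjusted p = 0.582 with an estimated correlation). Pdk4 was at 3.07 ± 0.58. Kupffer cell genes rose in 3 of 23 cases and fell in 1, or 4 and 1 adjusted over the list alone (adjusted p = 0.00257, adjusted p = 0.601 with an estimated correlation). Hmox1 was the largest of these rises at 3.16 ± 0.19. With median centring the medians of the last 4 lists, heat shock, ribosome biogenesis, fatty acid oxidation and Kupffer cell, turned negative, at -0.23, -0.15, -0.44 and -0.03 against a median of all genes of -0.18. The direction of the test stayed upward in all 4, and none was then called.

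Pericentral hepatocyte genes fell in 5 of 23 cases and rose in 1 at 8 h, or 5 and 3 adjusted over the list alone (adjusted p = 0.0227, adjusted p = 0.656 with an estimated correlation). Lhpp was at -1.48 ± 0.19 and Gstm3, a glutathione transferase gene, at 0.88 ± 0.21. Oxidative phosphorylation genes fell in 4 of 46 cases and rose in 2, or 6 and 2 adjusted over the list alone (adjusted p = 0.0295, adjusted p = 0.511 with an estimated correlation). Ndufv2 was at -0.68 ± 0.12 and Ndufa10 at 0.55 ± 0.14, the latter at -0.14 with median centring. Median centring gave 162 rises and 2366 falls at 8 h. The slide as a block left 1414 genes and ended the calls of the heat shock, cytokine and oxidative phosphorylation lists. Without 8 h replicate 2 the count was 416 and the pericentral call ended, at a median of -0.15 against -0.44, and without 8 h replicate 3 the Kupffer cell and oxidative phosphorylation calls ended. The oxidative phosphorylation call also ended without background correction (adjusted p = 0.106), with an offset of 0 (0.122), with the software's own ratios (0.0981) and with the authors' value table (0.0898). The stricter filter ended the cytokine, heat shock, oxidative phosphorylation and pericentral calls, with the cytokine median at -0.04, and an intensity trend the pericentral call. The mean of all probes ended the heat shock call, as did leaving out either 48 h array. Of the 16 calls, 9 held under every alternative of processing, block and left-out array.

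At 24 h most of the changes of at least 2-fold were falls. Akr1c6, a steroid-metabolising aldo-keto reductase gene (chromosome 13, 4456428 to 4456487), had a log2 ratio of -4.09 ± 0.33, Inmt -3.53 ± 0.37, Akr1c20 -3.39 ± 0.18, the glutaminase gene Gls2 -3.37 ± 0.17 and liver glycogen phosphorylase, Pygl, -3.36 ± 0.20. The largest rises were those of Gsta1 at 3.43 ± 0.62, Lor, a gene of the cornified envelope of skin, at 3.43 ± 0.28, Gsta2 at 3.28 ± 0.41, S100a9, a gene abundant in neutrophils, at 3.04 ± 0.50, Mt2 at 3.03 ± 0.42 and the chemokine gene Ccl5 at 2.97 ± 0.50. In all, 908 genes rose and 1696 fell, 313 and 701 of them at least 2-fold.

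Drug metabolism genes fell in 24 of 32 cases at 24 h with 0 rises, or 27 and 0 adjusted over the list alone (median -1.52, adjusted p = 1.28e-21, adjusted p = 0.0685 with an estimated correlation). Cyp3a25 and Cyp2c29 had log2 ratios of -2.76 ± 0.24 and -2.42 ± 0.12, and Cyp2e1, the main activating enzyme of acetaminophen, -1.63 ± 0.26. Falls were found among genes of both ends of the liver lobule. Of 23 pericentral genes 13 fell and 0 rose, or 17 and 0 adjusted over the list alone (adjusted p = 1.63e-11, adjusted p = 0.194 with an estimated correlation). Glutamine synthetase, Glul, was at -2.91 ± 0.39. Of 24 periportal genes 18 fell and 0 rose, or 19 and 0 adjusted over the list alone (adjusted p = 5.51e-17, adjusted p = 0.058 with an estimated correlation). Pck1 was at -3.22 ± 0.15. Oxidative phosphorylation genes fell in 41 of 46 cases with 0 rises, or 42 and 0 adjusted over the list alone (median -0.92, adjusted p = 2.3e-31, adjusted p = 0.058 with an estimated correlation). Ndufs8 was at -1.54 ± 0.10 and Atp5c1 at -1.44 ± 0.07.

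Of 43 secreted protein genes 25 fell and 0 rose at 24 h, or 32 and 1 adjusted over the list alone (adjusted p = 9.07e-18, adjusted p = 0.119 with an estimated correlation). Klkb1 was at -2.52 ± 0.12 and Igf1 at -1.64 ± 0.11. Fatty acid synthesis genes fell in 21 of 27 cases with 0 rises, or 24 and 0 adjusted over the list alone (adjusted p = 9.5e-20, adjusted p = 0.107 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 27 cases with 0 rises, or 23 and 0 adjusted over the list alone (adjusted p = 3.62e-16, adjusted p = 0.236 with an estimated correlation). Thrsp and Sc5d stood at -3.34 ± 0.33 and -2.96 ± 0.19. Bile acid synthesis and transport genes fell in 20 of 34 cases and rose in 1, or 22 and 2 adjusted over the list alone (adjusted p = 1.2e-09, adjusted p = 0.0624 with an estimated correlation). The bile salt export pump gene Abcb11 was at -2.19 ± 0.18 and the efflux transporter gene Abcc4 at 0.77 ± 0.17. Gluconeogenesis and glycolysis genes fell in 15 of 35 cases and rose in 3, or 20 and 4 adjusted over the list alone (adjusted p = 6.12e-07, adjusted p = 0.119 with an estimated correlation). The gluconeogenic gene Fbp1 was at -2.90 ± 0.12, while Aldoa and Ldha, which act in glycolysis, were at 1.43 ± 0.24 and 1.08 ± 0.19. Sex-biased liver genes fell in 14 of 29 cases and rose in 1, or 15 and 2 adjusted over the list alone (adjusted p = 1.21e-07, adjusted p = 0.119 with an estimated correlation). Cyp3a16 was at -2.20 ± 0.26 and Cyp2a4 at 1.52 ± 0.11.

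Heat shock genes rose in 10 of 24 cases at 24 h with 0 falls, or 13 and 2 adjusted over the list alone (adjusted p = 3.79e-06, adjusted p = 0.119 with an estimated correlation). The chaperone gene Hsp90aa1 was at 2.97 ± 0.26. NRF2 targets rose in 18 of 38 cases and fell in 5, or 20 and 6 adjusted over the list alone (adjusted p = 6.72e-07, adjusted p = 0.21 with an estimated correlation). Srxn1 was at 2.83 ± 0.33 and Gstm1 at -1.58 ± 0.25. The Gstm1 probe is placed on chromosome 5 and those of Gstm2 and Gstm3 on chromosome 3, so its value may not be that of Gstm1. Probes of other lists were not checked in this way. Ribosome biogenesis genes rose in 12 of 40 cases with 0 falls, or 21 and 0 adjusted over the list alone (adjusted p = 7.48e-13, adjusted p = 0.217 with an estimated correlation). Nop56 was at 1.44 ± 0.13. Of 36 immediate early genes 8 rose and 0 fell, or 10 and 0 adjusted over the list alone (adjusted p = 2.81e-08, adjusted p = 0.236 with an estimated correlation). The neutrophil list had 3 rises of 25 and 0 falls, or 6 and 0 adjusted over the list alone (adjusted p = 0.00286, adjusted p = 0.119 with an estimated correlation). These were S100a9, S100a8 at 1.81 ± 0.26 and Cxcr2 at 0.68 ± 0.14. Acute phase genes rose in 14 of 40 cases and fell in 5, or 15 and 5 adjusted over the list alone (adjusted p = 0.00377, adjusted p = 0.127 with an estimated correlation). Integrated stress and unfolded protein response genes rose in 9 of 39 and fell in 3, or 12 and 5 adjusted over the list alone (adjusted p = 0.019, adjusted p = 0.582 with an estimated correlation). With median centring the medians of these last 2 lists were -0.32 and -0.07 against a median of all genes of -0.07. The direction of the test stayed upward in both, and neither was then called. Median centring gave 26 rises and 732 falls at 24 h. The software's own ratios gave 4206 genes and the slide as a block 1520, and without 24 h replicate 3 the count was 1356 and the integrated stress call ended. The stricter filter ended the integrated stress and neutrophil calls and the authors' value table the acute phase call, and the other 14 of 17 calls held under every alternative of processing, block and left-out array.

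At 48 h 4290 genes rose and 3223 fell, more than at any other time point with loess, whereas with median centring the count was largest at 3 h, at 6023 genes against 2917 at 48 h. The largest falls were those of Rgn, or regucalcin (chromosome X, 20138932 to 20138991), at -4.92 ± 0.31, Sult2a8 at -4.75 ± 0.29, Car3 at -4.68 ± 0.47, Cyp2c54 at -4.53 ± 0.18, Akr1c6 at -4.26 ± 0.33 and Cyp3a11 at -4.17 ± 0.23. The rises were led by Gsta1 at 3.94 ± 0.62, the macrophage scavenger receptor gene Marco at 3.76 ± 0.73, Apoa4 at 3.72 ± 0.46, S100a9 at 3.66 ± 0.50, Afp, the alpha-fetoprotein gene of fetal liver, at 3.66 ± 0.25 and the lipid droplet gene Cidec at 3.52 ± 0.35.

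Of 41 monocyte and recruited macrophage genes 21 rose and 2 fell at 48 h, or 22 and 3 adjusted over the list alone (adjusted p = 5.03e-05, adjusted p = 0.236 with an estimated correlation). Lgals3 was at 2.65 ± 0.45 and Trem2 at 1.43 ± 0.18. Neutrophil genes rose in 13 of 25 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.00257, adjusted p = 0.119 with an estimated correlation). S100a8 was at 3.41 ± 0.26 and Chil3 at 3.27 ± 0.35. Kupffer cell genes rose in 9 of 23 cases and fell in 2, or 10 and 2 adjusted over the list alone (adjusted p = 0.00696, adjusted p = 0.653 with an estimated correlation). The lymphocyte list was called down with 4 falls and 1 rise of 30, and 0 of either adjusted over the list alone (adjusted p = 0.0105, adjusted p = 0.469 with an estimated correlation). Zap70 was at -1.59 ± 0.39. Of 36 cytokine and chemokine genes 11 rose and 3 fell, or 15 and 3 adjusted over the list alone (adjusted p = 0.0309, adjusted p = 0.241 with an estimated correlation). The monocyte chemokine gene Ccl2 was at 1.85 ± 0.21. Biliary and progenitor genes rose in 10 of 31 cases and fell in 1, or 11 and 2 adjusted over the list alone (adjusted p = 0.0121, adjusted p = 0.307 with an estimated correlation). Tnfrsf12a was at 3.08 ± 0.38 and Anxa2 at 2.81 ± 0.53. Stellate cell and matrix genes were not called, with 8 rises and 4 falls of 39, the same adjusted over the list alone (adjusted p = 0.205). Endothelial genes were not called either, with 7 rises and 1 fall of 36, the same adjusted over the list alone (adjusted p = 0.297). Col4a1 and Lyve1 were at 1.93 ± 0.19 and 1.62 ± 0.29. Adipose and pancreas genes were called at no time point, with 4 rises and 4 falls of 11 (adjusted p = 0.702) and 0 rises and 1 fall of 16 (adjusted p = 0.293) at 48 h.

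In the S phase and DNA replication list 18 of 38 genes rose and 2 fell at 48 h, or 19 and 3 adjusted over the list alone (adjusted p = 0.00528, adjusted p = 0.41 with an estimated correlation). The replication licensing gene Cdt1 was at 1.40 ± 0.21 and Mcm6 at 1.24 ± 0.20. In the G2 and mitosis list 4 of 32 rose and 0 fell, or 1 and 0 adjusted over the list alone (adjusted p = 0.741). The mitotic cyclin gene Ccnb1 was at -0.12 ± 0.12. Only 32 of 50 genes of that list were tested. Of 33 p53 targets 14 rose and 3 fell, or 15 and 3 adjusted over the list alone (adjusted p = 0.00134, adjusted p = 0.119 with an estimated correlation). Cgref1 was at 3.18 ± 0.09 and Cdkn1a at 2.80 ± 0.27. Ribosome biogenesis genes rose in 29 of 40 cases with 0 falls, or 32 and 0 adjusted over the list alone (adjusted p = 1.68e-10, adjusted p = 0.241 with an estimated correlation). Ddx21 was at 1.57 ± 0.16. In control livers this list fell from 3 to 48 h, so the ratio alone does not tell which side moved. Hypoxia genes rose in 16 of 27 cases and fell in 3, the same adjusted over the list alone (adjusted p = 0.00212, adjusted p = 0.245 with an estimated correlation). Ldha was at 2.61 ± 0.19 and Vegfa at -0.98 ± 0.11. Immediate early genes rose in 17 of 36 cases with 0 falls, the same adjusted over the list alone (adjusted p = 5.82e-05, adjusted p = 0.386 with an estimated correlation). NRF2 targets rose in 19 of 38 cases and fell in 6, or 20 and 8 adjusted over the list alone (adjusted p = 0.00361, adjusted p = 0.41 with an estimated correlation).

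Pericentral genes fell in 20 of 23 cases at 48 h with 0 rises, or 21 and 0 adjusted over the list alone (median -2.67, adjusted p = 3.96e-12, adjusted p = 0.188 with an estimated correlation). Glul was at -3.94 ± 0.39 and Cyp2e1 at -3.03 ± 0.26. Periportal genes fell in 17 of 24 and rose in 3, or 17 and 4 adjusted over the list alone (median -0.99, adjusted p = 0.000167, adjusted p = 0.141 with an estimated correlation). Cyp2f2 was at -3.02 ± 0.13 and Apoa4 at 3.72 ± 0.46. Drug metabolism genes fell in 25 of 32 cases with 0 rises, or 26 and 0 adjusted over the list alone (adjusted p = 2.09e-14, adjusted p = 0.107 with an estimated correlation). Secreted protein genes fell in 34 of 43 cases and rose in 1, or 37 and 1 adjusted over the list alone (adjusted p = 7.84e-18, adjusted p = 0.119 with an estimated correlation). Plasminogen, Plg, was at -2.46 ± 0.13 among the secreted protein genes, and Ces3a at -3.68 ± 0.21 among the drug metabolism genes. Bile acid genes fell in 20 of 34 cases and rose in 2, or 21 and 2 adjusted over the list alone (adjusted p = 2.9e-06, adjusted p = 0.107 with an estimated correlation). Sex-biased genes fell in 17 of 29 with 0 rises, or 19 and 0 adjusted over the list alone (adjusted p = 2.36e-08, adjusted p = 0.119 with an estimated correlation). Fatty acid synthesis genes fell in 17 of 27 and rose in 1, the same adjusted over the list alone (adjusted p = 3.76e-06, adjusted p = 0.241 with an estimated correlation). Cholesterol synthesis genes fell in 12 of 27 with 0 rises, or 14 and 0 adjusted over the list alone (adjusted p = 0.000137, adjusted p = 0.578 with an estimated correlation). Oxidative phosphorylation genes fell in 25 of 46 cases and rose in 7, or 26 and 7 adjusted over the list alone (adjusted p = 9e-05, adjusted p = 0.241 with an estimated correlation). Cox6c was at -1.36 ± 0.18 and Cycs at 1.64 ± 0.25. The median of this list flipped from -0.45 to 0.21 with median centring, and the list was then not called. Median centring gave 2529 rises and 388 falls at 48 h and the slide as a block 3670 genes, with the cytokine list no longer called. Without 48 h replicate 3 the count was 3397 and the lymphocyte call ended, and without 48 h replicate 1 the Kupffer cell, S phase, biliary and cytokine calls ended. The stricter filter ended the NRF2, S phase, biliary, cytokine, lymphocyte, neutrophil and p53 calls, with the cytokine and neutrophil medians at -0.44 and -0.21 against 0.20 and 0.28. The neutrophil median was 0.49 without 48 h replicate 1 and 0.18 without 48 h replicate 3, and the cytokine median was 0.11 without the latter. The cytokine call also ended with median centring and without background correction. Of the 21 calls, 12 held under every alternative of processing, block and left-out array.

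**Figure D2:**
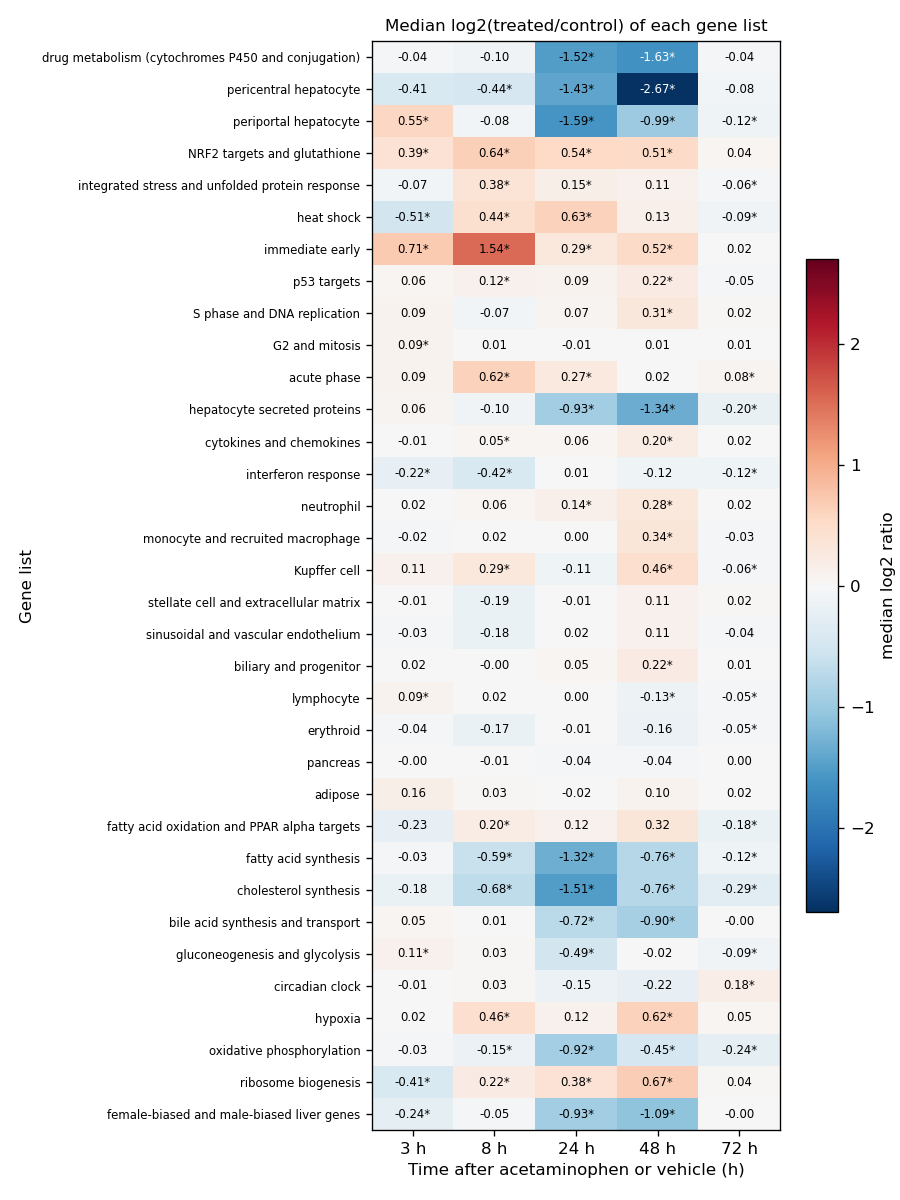
Median log2 ratio of treated over control of the tested genes of each of 34 lists (rows) at each time point (columns, hours; colour scale in log2 units, 2 arrays per time point), with an asterisk where camera at the preset correlation called the list. The pericentral median falls from -0.44 at 8 h to -2.67 at 48 h and is -0.08 at 72 h, and no call held with an estimated correlation.

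At 72 h no gene passed limma's test after adjustment (smallest adjusted p 0.151), and 762 genes, 3.19%, had an unadjusted p under 0.05. This test pools the spread over time points. Across genes, the difference between the 2 arrays divided by 2 had an SD of 0.125 at 72 h, against 0.148 to 0.183 at other time points. The pooled spread may thus be too wide at 72 h and too narrow at 48 h. The count of 0 at 72 h does not show that no gene changed. Genes far from control at 48 h had ratios close to 0, such as Cyp2e1 at -0.06 ± 0.26, Hmox1 at 0.05 ± 0.19, Cdkn1a at -0.17 ± 0.27 and Ccl2 at -0.01 ± 0.21. Among the members of the lists the largest ratios were those of the haemoglobin gene Hba-a1 at -2.07 ± 0.81, the urinary protein gene Mup20 at -1.92 ± 0.58 and Hbb-bt at -1.66 ± 0.80, none of which passed and which were picked after their values were seen. Small shifts of lists were still called for 15 of 34 lists, led by oxidative phosphorylation, whose median was -0.24 and of whose 46 genes 10 fell adjusted over the list alone and 0 over all genes (adjusted p = 3.11e-28, adjusted p = 0.058 with an estimated correlation). Cholesterol synthesis genes had a median of -0.29, with 1 of 27 falling adjusted over the list alone and 0 over all genes (adjusted p = 7.75e-10, adjusted p = 0.353 with an estimated correlation). Secreted protein genes had a median of -0.20 (adjusted p = 2.57e-06, adjusted p = 0.322 with an estimated correlation), and fatty acid oxidation genes of -0.18 (adjusted p = 2.6e-05, adjusted p = 0.443 with an estimated correlation). Gluconeogenesis genes had a median of -0.09 (adjusted p = 0.00013, adjusted p = 0.189 with an estimated correlation), and periportal genes of -0.12 (adjusted p = 0.000146, adjusted p = 0.141 with an estimated correlation). In each of these 2 lists 2 genes fell adjusted over the list alone. Circadian clock genes had a median of 0.18 (adjusted p = 0.00071, adjusted p = 0.188 with an estimated correlation), and acute phase genes of 0.08 (adjusted p = 0.0358, adjusted p = 0.236 with an estimated correlation). Integrated stress genes had a median of -0.06 (adjusted p = 0.00293, adjusted p = 0.479 with an estimated correlation), and interferon response genes of -0.12 (adjusted p = 0.00638, adjusted p = 0.724 with an estimated correlation). Fatty acid synthesis genes had a median of -0.12 (adjusted p = 0.0109, adjusted p = 0.511 with an estimated correlation), and erythroid genes of -0.05 (adjusted p = 0.0124, adjusted p = 0.367 with an estimated correlation). Heat shock genes had a median of -0.09 (adjusted p = 0.0347, adjusted p = 0.402 with an estimated correlation). The Kupffer cell median was -0.06 (adjusted p = 0.033, adjusted p = 0.731 with an estimated correlation), and the call turned to a rise with the slide as a block, at a median of 0.12. The lymphocyte median was -0.05 (adjusted p = 0.0379, adjusted p = 0.569 with an estimated correlation), and 0.02 without background correction. Of these 15 lists fry called 1, oxidative phosphorylation, and with the slide as a block 7 were still called in the same direction. That block turned the fatty acid synthesis and interferon medians to 0.05 and 0.02. The software's own ratios and the authors' value table each ended 8 calls, with the Kupffer cell test turned upward, no background correction ended 6, the stricter filter 5, median centring 2 and an intensity trend 1. Without 72 h replicate 3 the medians of 13 of 15 lists moved by over 1.5 times, to -0.06 for cholesterol synthesis, -0.06 for secreted proteins, -0.0016 for fatty acid oxidation, -0.05 for gluconeogenesis and 0.02 for the clock list. Those of the acute phase, integrated stress, interferon, fatty acid synthesis and heat shock lists went to 0.05, -0.0030, -0.01, -0.03 and -0.02, and those of the erythroid, Kupffer cell and lymphocyte lists to 0.00082, 0.0048 and 0.0030. Without 72 h replicate 1, 8 medians moved as far, such as fatty acid oxidation to -0.37. Without 72 h replicate 3 the calls of the Kupffer cell, erythroid, fatty acid oxidation, fatty acid synthesis, interferon and lymphocyte lists ended. Without 72 h replicate 1 those of the acute phase, gluconeogenesis, heat shock and periportal lists ended, and 5 of 15 calls held whichever of these arrays was left out. The Kupffer cell call also ended without 3 h replicate 3, and the lymphocyte call when either 8 h array was left out. Of the 5 calls, secreted proteins ended with the slide as a block and without background correction, and integrated stress with the software's own ratios and median centring, so that oxidative phosphorylation, cholesterol synthesis and the clock list, 3 of 15, held under every alternative of processing, block and left-out array. Leaving out 72 h replicate 1 gave 1 gene, other alternatives between 0 and 5, and the contrast with the mean of the other time points 617.

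**Figure D3:**
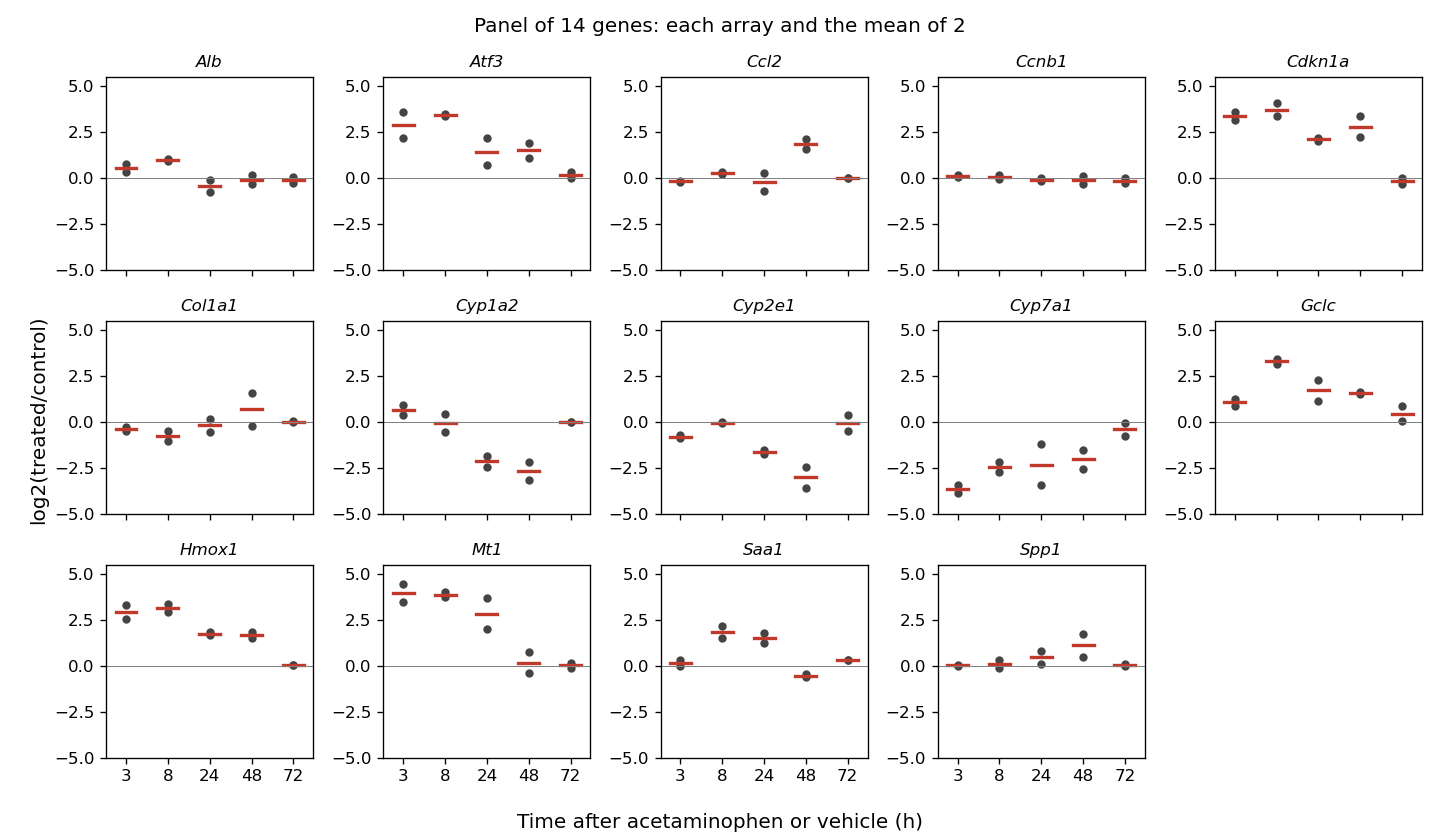
Log2 ratio of treated over control (y axis) of the 14 panel genes against time (x axis, hours), with a point per array and a bar at the mean of 2. Gclc is highest at 8 h (3.31), Cyp2e1 lowest at 48 h (-3.03), and the 72 h means lie between -0.40 for Cyp7a1 and 0.44 for Gclc.

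Differences between neighbouring time points, in which a constant dye effect cancels, were tested directly. From 3 to 8 h the ratio differed in 198 genes, 128 upward, led by Cxcl10 at 5.22 ± 0.37, Cxcl1 at 3.34 ± 0.36 and Bcl3 at 3.16 ± 0.16, against G6pc at -2.53 ± 0.38, Pck1 at -2.29 ± 0.22 and Pstpip2 at -1.86 ± 0.29. From 8 to 24 h 1507 genes differed, 592 upward, with Tardbp at 3.18 ± 0.24 and Ccl5 at 3.09 ± 0.71 against Chac1 at -4.69 ± 0.41, Rgs16 at -4.59 ± 0.36 and Slc25a47 at -4.38 ± 0.19. From 24 to 48 h 2501 genes differed, 1868 upward, with Chil3 at 4.02 ± 0.50, Afp at 3.91 ± 0.35 and Uts2 at 3.54 ± 0.39 against Saa2 at -3.20 ± 0.44, Sult2a7 at -2.96 ± 0.66 and Cyp2a4 at -2.83 ± 0.16. From 48 to 72 h 3964 genes differed, 1570 upward, with Rgn at 4.96 ± 0.43, Cyp2c54 at 4.38 ± 0.26 and Cyp3a11 at 4.30 ± 0.33 against Igfbp1 at -4.13 ± 0.73, Cidec at -3.75 ± 0.50 and Afp at -3.67 ± 0.35. Over all time points 5569 genes differed by the F test, with the smallest p for Aadac, Cgref1, Slc25a47, Trp53inp1, Ppp1r14b, Ndrg2, Herpud1 and Pon1. With the slide as a block limma called 0 genes in the differences between 3 and 8 h, 8 and 24 h, and 24 and 48 h, where 2486, 3624 and 5092 genes had an unadjusted p under 0.05. The same block left 1124 genes by the F test. The 48 and 72 h arrays lay on the same slides, so this block cannot move the differences between them, and 3213 genes were called there. With median centring limma called 0 genes between 3 and 8 h, with 1478 at an unadjusted p under 0.05. It gave 2 falls between 8 and 24 h, 523 rises and 2 falls between 24 and 48 h, 16 rises and 134 falls between 48 and 72 h and 1280 genes by the F test, and the software's own ratios gave 29 rises and 8 falls between 3 and 8 h.

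Single arrays also moved these counts. The count between 3 and 8 h was 4 without 3 h replicate 1, 549 without 3 h replicate 3, 8 without 8 h replicate 2, and 58 without either 72 h array. Between 8 and 24 h it was 545 without 8 h replicate 2 and 833 without 24 h replicate 3. Between 24 and 48 h it was 939 without 24 h replicate 3, 934 without 48 h replicate 3 and 1518 without 24 h replicate 1. Between 48 and 72 h it was 1597 without 72 h replicate 1, 1924 without 72 h replicate 3 and 1910 without 48 h replicate 3.

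Levels in control livers also differed between the arrays of different time points. The 3 h arrays shared no slide with the 48 and 72 h arrays, so those contrasts are also contrasts between slides. With the slide as a block 37 genes passed the F test over time, against 869 without it. When the fasted mice were fed again is not given in the sources used here. By the F test 869 genes differed between time points in the Cy3 channel, and against 3 h the count was 0 at 8 h (limma, smallest adjusted p 0.133, 1444 genes at an unadjusted p under 0.05), 549 at 24 h, 1774 at 48 h and 755 at 72 h. From 3 to 72 h the log2 level of Cyp7a1 changed by -3.37 ± 0.19, that of the actin gene Actg1 by -2.77 ± 0.29, and those of Slc16a5 and Noct by -2.33 ± 0.16 and -2.22 ± 0.23. The largest rises to 72 h were those of Zfp663 at 2.92 ± 0.35 and of Oprm1, Proser3, Mcidas and Hexim2, at 2.82 to 2.83. In the treated channel the same 5 genes rose by a median of 3.17. Of the 869 genes, 576 also differed in the treated channel of the same arrays. From 3 to 72 h 692 of the 869 had the same sign in both channels. The correlation was 0.755 across these genes, which are not independent replicates. Both channels are read from the same spots, so a spot, array or slide effect can move both the same way. This agreement cannot tell such an effect from a change in the livers. At 24 h the fatty acid hydroxylase genes Cyp4a31 and Cyp4a10 stood at -3.27 ± 0.42 and -3.23 ± 0.44 against 3 h and Sult2a4 at -4.71 ± 0.70. Over the same interval Lpin1 had risen by 2.73 ± 0.35 and the probe named Ren2 by 2.57 ± 0.32. That probe has no position among the probe coordinates used, so its value may not be that of Ren2. Ribosome biogenesis genes fell from 3 to 48 h in 24 of 40 cases with 0 rises, or 30 and 0 adjusted over the list alone (adjusted p = 2.62e-18, adjusted p = 0.438 with an estimated correlation). Heat shock genes fell in 11 of 24 cases with 0 rises, or 15 and 2 adjusted over the list alone (adjusted p = 2.35e-07, adjusted p = 0.438 with an estimated correlation). The change of the ratios of both lists from falls at 3 h to later rises may thus come partly from the control channel. The same holds for the return of the Cyp7a1 ratio towards 0 by 72 h. The F count was 37 with the slide as a block, 121 with median centring, 52 with the software's own ratios and 1744 with the scan day as a block. It was 58 without 3 h replicate 3, 90 without 3 h replicate 1, 174 without 24 h replicate 1, 295 without 24 h replicate 3, 522 without 48 h replicate 3, 174 without 72 h replicate 1, 127 without 72 h replicate 3 and 451 without 8 h replicate 3.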

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

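All tests of explanations in this part were chosen after the result was seen. By tests of the difference itself, the ratio of treated over control differed in 198 genes between 3 and 8 h, 1507 between 8 and 24 h, 2501 between 24 and 48 h, 3964 between 48 and 72 h and 5569 over all time points. With the slide as a block 0 genes differed in each of the earliest 3 of these comparisons by limma, at smallest adjusted p of 0.237, 0.0587 and 0.0604 and with 2486, 3624 and 5092 genes at an unadjusted p under 0.05. With median centring 0 differed between 3 and 8 h, with 1478 at an unadjusted p under 0.05. Between 3 and 8 h, 2 lists were called in opposite directions, heat shock with a median difference of 0.79 (adjusted p = 1.73e-12, adjusted p = 0.0863 with an estimated correlation) and ribosome biogenesis with 0.68 (adjusted p = 3.69e-23, adjusted p = 0.142 with an estimated correlation). With the slide as a block these differences were 0.88 (adjusted p = 5.67e-11) and 0.60 (adjusted p = 2.68e-22), although the heat shock call at 8 h alone ended under that block, and both calls at 8 h ended with median centring. Kupffer cell genes were called up at 48 h and down at 72 h, with a median difference of -0.58 (adjusted p = 0.00098, adjusted p = 0.51 with an estimated correlation). With the slide as a block this list was called up at both time points, at medians of 0.67 and 0.12, and its call at 72 h ended without 72 h replicate 3, so the opposite directions did not hold there. The 48 and 72 h arrays lay on the same slides, so the block cannot move the difference between them.

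No gene passed the test at 72 h, where the log2 ratios of the 2 arrays had SDs of 0.16 and 0.24. Compressed ratios were argued against by the spike-in controls, whose mean slope of observed on expected ratio was 0.883 on these arrays, with 0.830 as the lowest on any array. Dim signal was argued against by the 12424 genes well above background in both channels on every array, whose spread at 72 h was 0.474 of the lowest of the other time points. Control RNA in the treated channel stays open. The 2 arrays correlated at 0.266, but the dyes were never exchanged. A constant dye effect of probes would also make this correlation positive, so it cannot decide the question. Across time points, 72 h replicate 1 correlated at 0.256 with 3 h replicate 1 and at -0.098 with 48 h replicate 3. By 72 h treated livers may have returned towards the state of their controls, which the design names as a difference in time. Such a return may account for the pattern and was not tested apart from control RNA in the treated channel. Levels in control livers also differed between time points, so the ratio alone does not tell which side moved.

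Of 27 tested cornified envelope genes, a set chosen after its values were seen, 11 rose and 0 fell at 24 h, with a median of 2.36 among those that rose, and 7 rose at 48 h. Lor and Sprr1a had already risen at 8 h, by 1.52 and 1.12 (limma, adjusted p = 0.0125 and 0.00384). Skin in the treated samples would bring keratinocyte transcripts, but of 17 tested markers 0 rose and 2 fell at 24 h, with a median of 0.012, and the abundant keratins Krt14 and Krt10 were at 0.06 ± 0.08 and 0.15 ± 0.11. At 48 h, however, 4 markers rose (Krt5 at 1.02, Dsp at 1.33, Aqp3 at 1.18 and Perp at 0.53) and 2 fell, with a median of 0.16, so skin stays open for the 7 genes that rose then. A constant dye effect was argued against by the change at 24 h relative to the mean of the other time points, at a median of 1.94. A response of injured liver is one hypothesis that stays open, and cross-hybridisation among these similar genes was not tested.

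The 5 genes with the largest rise from 3 to 72 h in control livers, Zfp663, Oprm1, Proser3, Mcidas and Hexim2, rose by a median of 2.83. A change in vehicle-injected livers alone was argued against by the treated channel, where the same genes rose by a median of 3.17. With the slide as a block the median in control livers was 2.07. The 3 and 72 h arrays shared no slide, so this value rests on links through arrays of other time points. Differences between slides therefore stay open. Their deviations from the mean of each channel and time point correlated at a median of 0.915. This was higher than in 100 of 100 random sets of 5 other risers, whose highest was 0.868. The deviations entered the choice through the spread in the F test, which the genes of the random sets had also passed. They also mirror each other between the arrays of a time point, so few of them are independent. One signal shared by these probes, such as a common hybridising transcript or a labelling effect that differs between time points, is a candidate explanation, and a transcript that truly changes with time in both groups of mice stays open.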

How the results depend on the processing

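Leaving out both 72 h arrays was chosen after seeing the data. All other alternatives were fixed before the data were examined, apart from the factor that rescales the authors' value table. That factor was found by setting its values against the scanner files. Counts within 1.5 times the value in the report are not repeated, and the cause was not tested for any change below unless stated. The count of gene lists called, 79, ran from 62 with the stricter filter to 87 with median centring and was 55 with fry and 0 with an estimated correlation. The Cy5 channel in place of Cy3 gave 4527 genes differing between time points, quantile normalization of Cy3 alone 563 and no filter on dim probes 533, against 869.

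Median centring in place of loess gave 6023 genes at 3 h, 758 at 24 h and 2917 at 48 h, 0, 2, 525 and 150 genes in the differences between neighbouring time points, 1280 by the F test and 121 in control livers. It moved the median of all genes by -0.24 at 3 h, -0.17 at 8 h and 0.21 between 24 and 48 h. The software's own ratios gave 1058 genes at 3 h, 4206 at 24 h, 1 at 72 h, 37 between 3 and 8 h, 1278 between 24 and 48 h and 52 in control livers, with a median of all genes of -0.11 at 48 h. The authors' value table gave 1057 genes at 3 h, 4190 at 24 h and 1 at 72 h, with the same median of -0.11 at 48 h. No background correction gave 4875 genes at 24 h, 2 at 72 h, 400 between 3 and 8 h, 2885 between 8 and 24 h and 417 in control livers. An offset of 0 gave 1 gene at 72 h, 111 between 3 and 8 h, 1544 between 24 and 48 h and 249 in control livers. The stricter filter gave 1 gene at 72 h and 315 between 3 and 8 h, and array weights gave 5 at 72 h.

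The slide as a block, which takes 3 of the 5 residual degrees of freedom, gave 321 genes at 3 h (179 rises, 142 falls), 1414 at 8 h, 1520 at 24 h, 3670 at 48 h, 0 between 3 and 8 h, 0 between 8 and 24 h, 0 between 24 and 48 h, 1124 by the F test and 37 in control livers. With the replicate number as a block, which is also the scan day, 115 genes differed between 3 and 8 h and 1744 in control livers, and the counts at the time points were 1815, 3066, 2688, 7765 and 0. All 79 list calls kept their direction under this block. Each day holds 1 array of every time point, so this block leaves the log2 ratios as they were. It is therefore no check of their direction. The replicate numbers cannot pair mice across time points, since each liver was taken at a single time point. Correlations between time points of the difference between the 2 arrays ran from -0.12 to 0.29, with 4 of 10 above 0.1. These can hold slide or scan-day differences and do not test a pairing. Fitting only the arrays of the time points compared, and so on fewer residual degrees of freedom, gave 889, 1139, 716 and 3266 genes at 3, 8, 24 and 48 h (584 rises and 555 falls at 8 h), and 1, 669, 217 and 2589 in the neighbouring differences. Without both 72 h arrays 58 genes differed between 3 and 8 h and 255 in control livers. Against the mean of the other time points the counts were 1100 at 8 h (577 rises, 523 falls), 1328 at 24 h and 617 at 72 h. Of the genes called at 3, 8, 24 and 48 h, 978, 831, 1105 and 5014 were called the same way in that contrast and 9, 11, 2 and 10 the opposite way.

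With a single array left out, the remaining array of its time point is assumed to vary like the others. The counts then ran from 403 to 2029 at 3 h (264 rises and 139 falls without 3 h replicate 1, 854 and 273 without 3 h replicate 3), from 416 to 3326 at 8 h, from 1356 to 2723 at 24 h, from 3397 to 7335 at 48 h and from 0 to 1 at 72 h. In the neighbouring differences they ran from 4 to 549, 545 to 1683, 934 to 3323 and 1597 to 4689. The F test gave 3721 to 5783 genes, control livers 58 to 941 and the lists 75 to 85.

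Of 563 values of named genes, 7 changed sign with median centring, 142 no longer passed and 8 passed in addition. Aquantile scaling moved none of the 563 across the threshold. It scales average intensities and leaves the log2 ratios as they were, so it could not move the ratios and is no check of them. The 7 were Abcc2 at -0.14, Cd22 at -0.12 and Hal at -0.22 at 3 h, Ndufa10 at -0.14 and Atp5d at -0.42 at 8 h, and Nr1h3 at 0.20 and Elane at 0.13 at 48 h. The mean of all probes turned Hspa4 at 8 h to -0.15, its probes having been called in opposite directions. Against the mean of the other time points 16 changed sign, as that contrast allows where other time points moved further: Pfkfb1 at 0.036 at 3 h, then at 8 h Idi1 at 0.20, Fdps at 0.23, Ndufs1 at 0.0083, Lhpp at 0.19 and Oat at 0.54. At 24 h these were Hmox1 at -0.20, Gdf15 at -0.49, Cdkn1a at -0.33 and Jun at -0.60, and at 48 h Igfbp1 at -0.36, Hmox1 at -0.30, Egr1 at -1.54, Cyp7a1 at 0.19, Gclc at -0.044 and Atf3 at -0.47. Signal over background limits dim genes, since 45.1% of spots were well above background in Cy5 on 72 h replicate 1 and 45.6% on 3 h replicate 1, against 76.6% on 48 h replicate 3.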
